A study of Mus musculus with 12 samples.

How the data were processed

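Liver RNA of mice at postnatal day 17 (P17) or postnatal day 28 (P28) was measured on 12 single-colour ABI1700 arrays, which read chemiluminescence from digoxigenin-labelled cRNA. Per the labels, Hdac3-null livers had lost the histone deacetylase gene Hdac3 through Cre recombinase driven by the albumin promoter, and control livers came from wild-type or heterozygous mice. RNA of 5 mice was combined into 1 pool. Each of the 4 groups held 2 pools and 3 arrays: the first pool was hybridised in duplicate on separate chip lots and the second pool once. The 2 arrays of a first pool were averaged, so n = 2 pools per group and 8 pools in all, and p-values measure the spread between 2 pools of 5 mice and between the runs in which they were hybridised. The number of pools limits the precision of every value.

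The value table deposited by the authors holds intensity on a linear scale for 33012 probes and names each column by its sample. Its distributions fall into 3 sets of 4 arrays: within a set, the largest gap between 2 cumulative distributions was 0.0034, and between sets the smallest was 0.1824, so the deposited intensity values had been brought to 1 distribution within each set. The second pools of the 4 groups form 1 set, with medians of 854.46 to 862.68. The P17 first pools form another, with medians of 405.04 to 411.02, and the P28 first pools the last, with medians of 489.76 to 491.8. The software behind this step is not given in the sources used here. The 12 scanner files are copies of 3 exports that hold 4 arrays each, and their columns carry no sample name. The file attached to the P28 Hdac3-null second pool is a copy of the export of the P28 first pools, while the value table places that sample with the second pools; the value table was followed, and the run sets rest on its distributions alone. The 52 scanner columns of per-sample values were therefore assigned to no sample. Per the file headers they hold a signal intensity, a signal-to-noise score and a flag for each spot. All 12 columns of the value table had a scanner column of almost identical rank order, and the highest rho to any other column was 0.877. Such a match could assign the scanner columns and place the P28 Hdac3-null second pool, but it was used for neither. The value table left 2867 of 396144 cells empty (0.72%), against 2866 scanner readings flagged bad (flag over 5000). The share of probes with a signal-to-noise score of at least 3 ran from 36.5% to 48.2% per array.

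The intensities were quantile-normalized over all 12 arrays, raised to a floor at the 5th percentile (174.7), converted to log2 and averaged within a pool. The design written before the data were examined asked for a signal-to-noise score of 3 on every array of a group. Since the scanner columns have no sample name and the match by rank order was not used to assign them, its fallback was used. The fallback leaves out only probes at the floor on every array, and no probe was. A total of 33010 probes gave every term of the model and were tested. A stand-in for the filter was added after the data were seen: the signal level (890, or 9.80 on the log2 scale) under which the same share of values lies as scanner readings have a score under 3 (58.6%), required on every array of at least 1 group, which 12925 probes passed. A probe can pass only through a group in which it is high, which favours calls against that group. All counts above the detection level and the calls over named probes carry this limit. A probe under this level on every array of a group is called not well above background there, and its fold is given as at least N-fold against the higher of that level and the group's own mean. Where only some arrays of a group reach the level, their number is given, and a fold with arrays raised to the level is the ratio after each array under it was set to it.

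Groups were compared with limma 3.58.1 (lmFit and eBayes, 4 groups, 8 pools, 4 residual degrees of freedom, no covariate) in R 4.3.3, and calls had a Benjamini-Hochberg adjusted p under 0.05. Fold changes carry limma's standard error (SE). Tests of overlap were one-sided Fisher's exact tests. The contrasts were null against control at each age, the difference between these, and P28 against P17 in each genotype. Pool numbers were checked for pairing: over 12902 probes above the detection level, the difference between first and second pool correlated between groups with r = 0.52 to 0.649 in 6 pairs of groups. Because of this correlation a replicate block by pool was also fitted, although the first pools span 2 run sets, and its counts stand beside each result that it moved by more than 1.5 times. Each null-against-control difference of a pool lies within 1 run set. The P28-against-P17 difference of the first pools lies across 2 sets and that of the second pools within 1 set, so values per pool are given.

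On simulated pools with the same spread, the P28 comparison over 33012 probes called 0%, 0%, 30% and 50% of 50 probes each that were changed by 1, 2, 3 and 4 on the log2 scale, with 1 false call among 41. Over the 12925 probes above the detection level it called 0%, 28%, 58% and 78%. With the block and the detection level together it called 12%, 70%, 76% and 96%, with 6 false calls among 133. An unchanged P17 comparison gave 0 calls in each fit. The simulation gave all 4 groups the same pool difference and took the spread of the fit with the block, which favours the block. The probes above the detection level were those of the real data. False calls from choosing probes that are high in 1 group therefore cannot show here.

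Probe identifiers were named through RefSeq accessions of assembly GRCm38.p6, or otherwise through its gene symbols and synonyms, as for Dcdc5. In this way 317 probes (0.96%) received 1 symbol, 311 symbols in all. The other 32695 are reported by their identifier only, 27930 of them Celera gene identifiers. Of 42 gene lists and cell type marker lists fixed in advance, with 800 symbols, 7 had a named probe and 8 symbols were covered; no list had 80% of its members named. Tests of lists were therefore void and not run, and single members are given as values. A gene with several probes is represented by the brightest. Hdac3 had no probe named here, so the loss of its transcript was not checked and the genotypes rest on the labels. The lists of sex chromosome and sex-biased genes had no named probe, so the sex of the pooled mice was not checked. Differences in sex between pools were therefore not told apart from age or genotype.

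Named genes followed a rule fixed in advance: for each genotype comparison the 6 highest and 6 lowest log2 fold changes among called probes with a symbol, for each other comparison the 5 smallest adjusted p per direction, and for each list the called members or otherwise 1 member with the largest change. Because this gave few genes, 12 more were chosen after their values were seen: those with an adjusted p under 0.05 over the 137 named probes above the detection level, with no block in any comparison, or with the block at P28 and a log2 difference of at least 1.5. The bound of 1.5 was set after the values and the changes of sign between settings had been seen, partly to shorten the text, and called genes under it that no other rule names were not followed across settings. Stat5b was added as the other measured member of the Stat5a list. The adjustment over these 137 probes is called the adjustment over named probes. Its p-values come from the fit above the detection level, with or without the block, which estimates the spread anew. They are thus not the p-values of the fit over all probes adjusted over a smaller family. Each SE in the text is that of the fit over all probes with no block. Also added after the data were seen were the fits with the detection level, the run set as a block over 8 pools, and a comparison of genotype over both ages together. Alternatives listed before the data were examined were 75th-percentile scaling, the deposited values without further normalization, normexp background correction, other floors and filters, either duplicate array alone, 12 unaveraged arrays, blocks, other variance settings, and leaving out each pool. Figures were drawn with matplotlib 3.10.9.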

Results

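The study asked which liver transcripts change when Hdac3, the catalytic histone deacetylase of the NCoR/SMRT corepressor complexes, is lost from hepatocytes, at P17 and at P28. The data are 12 arrays of 8 RNA pools: 2 pools each of P17 control, P17 Hdac3-null, P28 control and P28 Hdac3-null liver. Between 36.5% and 48.2% of probes per array had a signal-to-noise score of at least 3. Over 12858 probes above the detection level with a value on every array, duplicate arrays of 1 pool correlated with r = 0.965 to 0.980, and arrays of the first and second pool of a group with r = 0.924 to 0.952. The first principal component (28.9% of variance) placed both null pools above the control pools of the same age and pool number at P17 and at P28. The second (24.2%) placed every second pool above the first pool of its group. On the third (18.3%) the P28 controls lay lowest, between -63.41 and -33.04.

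**Figure D1:**
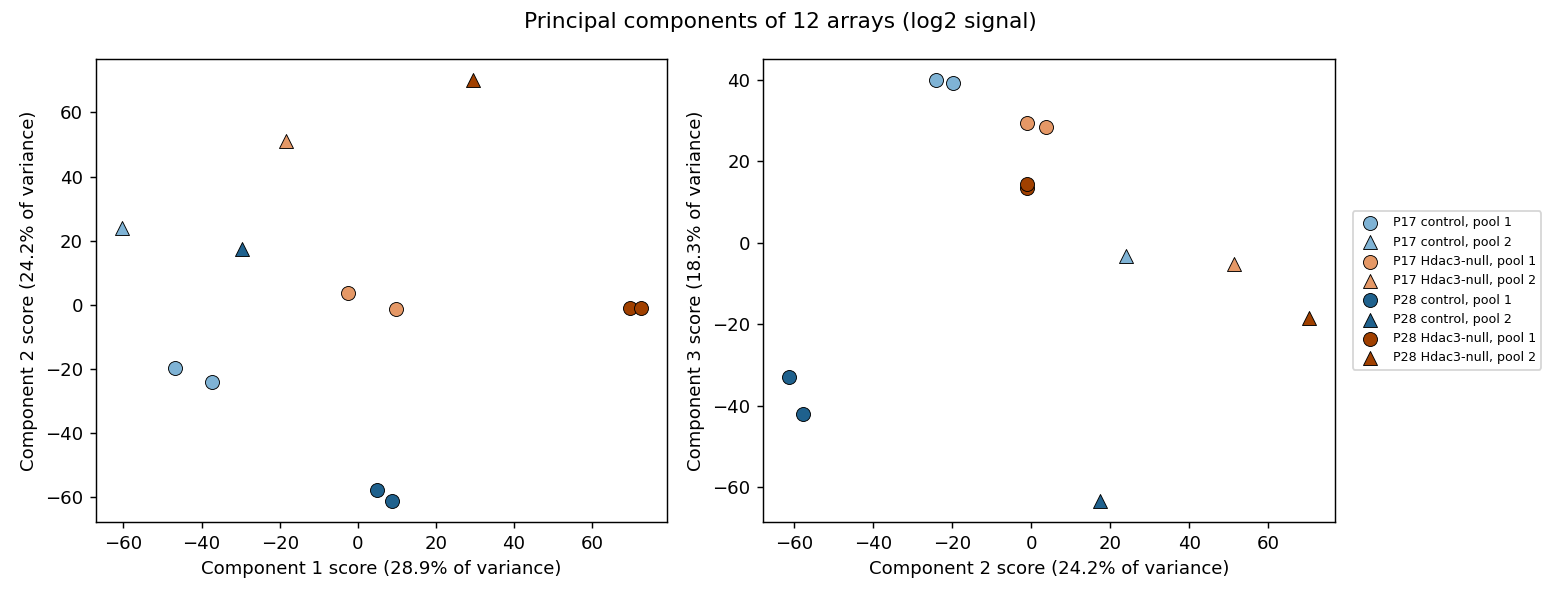
Principal component scores of the 12 arrays (left, components 1 and 2; right, components 2 and 3), coloured by group, with circles for first-pool arrays and triangles for second-pool arrays. P28 null arrays reach 69.74 to 72.65 (first pool) and 29.5 (second pool) on component 1, against 4.82 to 8.82 and -29.6 for P28 control arrays.

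At P28, loss of Hdac3 went with 131 changed probes, 83 higher and 48 lower (limma, adjusted p under 0.05, n = 2 pools per group). 3 of them carried a gene name. Wfdc2, a secreted whey-acidic-protein-domain protein of epithelia, rose 15.1-fold, from 10.04 ± 1.14 to 13.95 ± 0.38 log2 signal (SD, n = 2 pools; log2 fold change 3.91, SE 0.58, adjusted p = 0.049). Lgals1, which encodes the beta-galactoside-binding lectin galectin-1, rose 5.86-fold, from 12.82 ± 0.22 to 15.37 ± 0.08 (2.55, SE 0.38, adjusted p = 0.049). Dpp9, a cytosolic dipeptidyl peptidase, fell 6.42-fold, from 16.60 ± 0.47 to 13.92 ± 0.04 (-2.68, SE 0.36, adjusted p = 0.035). Each moved the same way in both pools: 4.99 and 2.84 for Wfdc2, 2.65 and 2.45 for Lgals1, -2.32 and -3.05 for Dpp9. In P28 control liver 1 of 3 arrays reached the detection level for Wfdc2; with the others raised to that level its fold was 12.4. None of these 3 calls was kept when any 1 of the 8 pools was left out or with the run set as a block over 8 pools.

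Adjusted over named probes, a family chosen after the values were seen, 5 genes rose at P28 and 3 fell, the preceding genes among them. Hsd3b4, of the 3-beta-hydroxysteroid dehydrogenase family, fell 36.3-fold, from 15.07 ± 0.01 to 9.89 ± 1.10 (log2 -5.18, SE 0.82, adjusted p = 0.013 over named probes and 0.060 over all probes). For Hsd3b4, 1 of 3 P28 null arrays reached the detection level, and the fold was 28.7 with the others raised to it. This gene entered the named family only through P28 control liver, the group it is compared with here, which favours the call. Dcdc5 fell to a level not well above background, at least 2.67-fold (log2 -2.02, SE 0.46, adjusted p = 0.038 over named probes). Aldh3a2, the fatty aldehyde dehydrogenase, rose 3.26-fold (1.70, SE 0.33, adjusted p = 0.012 over named probes). Lgals7, which encodes galectin-7, rose 3.59-fold (1.84, SE 0.37, 0.016) and Lst1, a leukocyte-expressed transcript, 2.34-fold (1.23, SE 0.33, 0.038). With the replicate block by pool the same family gave 22 calls at P28, 12 higher and 10 lower, which included all 8. Among those added were the iodothyronine deiodinase Dio1, which activates thyroid hormone (log2 -1.75, adjusted p = 0.022), the transcription factor gene Jun (1.69, 0.042), Bcl2a1b, of the anti-apoptotic Bcl2 family (2.18, 0.042), the eosinophil-associated ribonuclease Ear1 (2.06, 0.016; 2 of 3 P28 control arrays over the detection level) and Trim59, which was not well above background in P28 control liver (at least 1.93-fold higher, 0.047), together with the list genes Stat5a and Plin3 (0.042 for each).

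Members of the fixed lists were few. Stat5a, a transcription factor of growth hormone signalling, differed by 1.70 at P28 (SE 0.44, adjusted p = 0.22 over all probes, 0.010 adjusted over the list alone) and by 0.78 at P17 (SE 0.44), while Stat5b, the other measured member of its list, differed by -0.21 (SE 0.43) and 0.02 (SE 0.43). Plin3, a lipid droplet coat protein, differed by 0.92 at P28 and 0.89 at P17 (SE 0.33 for each; adjusted p = 0.42 and 1 over all probes, 0.026 and 0.030 adjusted over the list alone, of which it was the only member measured). G6pc, the catalytic subunit of glucose-6-phosphatase and the only measured member of the gluconeogenesis list, differed by -1.10 at P17 and 0.89 at P28 (SE 0.35 for each; adjusted p = 0.84 and 0.47 over all probes, 0.014 and 0.034 over the list alone). Fgf21, a hepatic hormone induced by PPAR alpha, differed by 1.68 at P28 (SE 0.67), with 0.64 in the first and 2.71 in the second pools. Its adjusted p was 0.49 over all probes and 0.039 over the list alone, of which it was the only member measured. For a list with only 1 measured member the latter is the unadjusted p. For Stat5a and Fgf21 2 of 3 P28 control arrays reached the detection level. Cebpb, a hepatocyte transcription factor, differed by 0.35 (SE 0.38), the cholangiocyte and progenitor marker Krt23 by -0.91 (SE 0.61), and the erythroid marker Hba-a1 by 0.13 (SE 0.34), none of them called. Adjusted over the 8 list genes together, 1 was called at P28 and 0 at P17; over all probes neither age had any.

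Probes without a name gave the largest changes. mCG119412.1 rose at least 131-fold (adjusted p = 0.014) and mCG2777.1 at least 164-fold (0.025), with arrays under the detection level raised to it; for each, 1 of 3 P28 control arrays reached that level. mCG20398.1 and mCG6998.2 were not well above background in P28 null liver and fell at least 98.9-fold and 58.4-fold (adjusted p = 0.014 for each). The replicate block by pool called 246 probes at P28, 146 higher and 100 lower, and shared 129 of the 131. Above the detection level 521 were called, which included all 131. The count fell to between 0 and 28 when any 1 of the 8 pools was left out, and to 5 with the run set as a block over 8 pools.

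**Figure D2:**
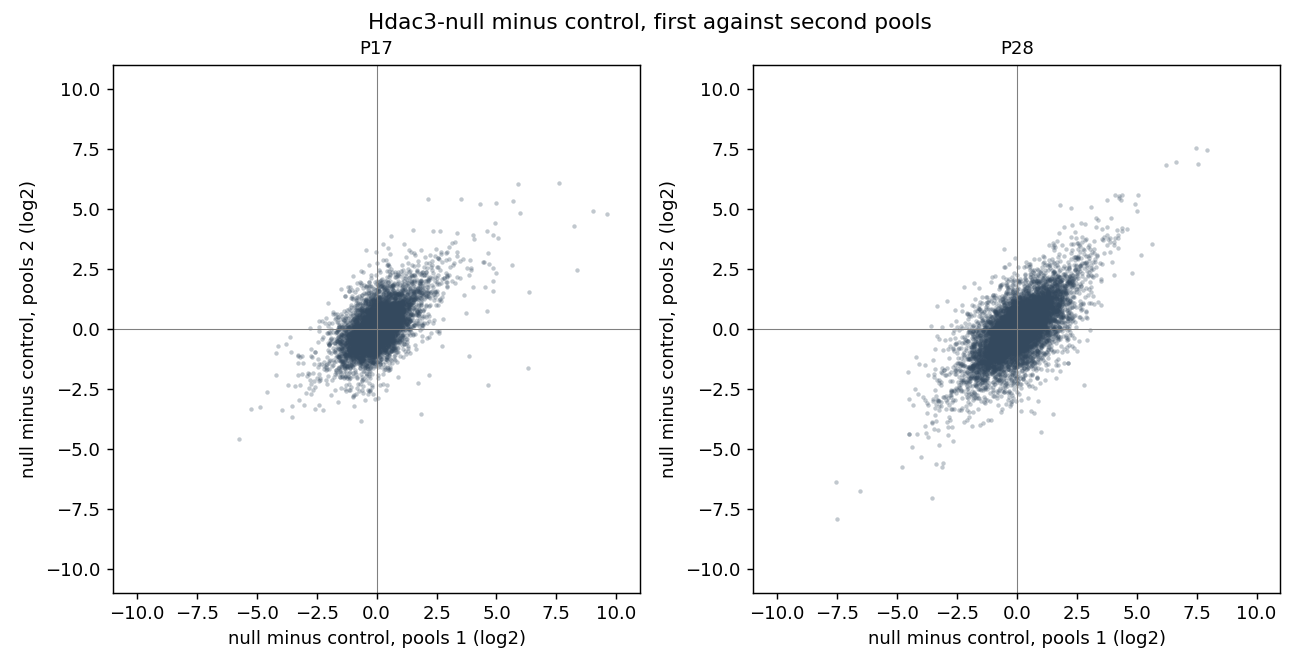
Null minus control log2 difference of 12765 probes without a symbol above the detection level, first pools (x axis) against second pools (y axis), at P17 (left) and P28 (right); each point is 1 probe. Points spread further along the diagonal at P28; over 12902 probes above the detection level, named ones included, the difference correlated between pools with r = 0.622 at P17 and 0.691 at P28.

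At P17, 15 probes changed, 13 higher and 2 lower in Hdac3-null liver, and none carried a gene name. Over named probes, Sult5a1, a cytosolic sulfotransferase, rose 6.91-fold, from 11.42 ± 0.57 to 14.21 ± 0.18 (SD, n = 2 pools; log2 2.79, SE 0.45, adjusted p = 0.041, and 0.15 over all probes). With the replicate block by pool, Lgals1 (1.61, SE 0.38) and Aldh3a2 (1.41, SE 0.33) were called as well over named probes, each with adjusted p = 0.034, and so was the major urinary protein probe Mup1 (2.34, SE 0.49, adjusted p = 0.050, against 0.067 with no block). Wfdc2 and Dpp9 differed by 0.17 (SE 0.58) and 0.15 (SE 0.36). The block called 5 probes, all among the 15, and the detection level 96, which included all 15. The run set as a block over 8 pools called 0. Leaving out 1 pool gave between 0 and 5.

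5 probes rose at both ages, against 0.0327 if the lists were independent (one-sided Fisher's exact test, p = 1.1e-10), and 0 fell at both. Probes are not independent, so the p is descriptive. Both comparisons also use the same estimate of spread for a probe, which by itself makes shared calls likelier than this expectation. The replicate block gave 3 shared calls, and there were 0 without any 1 of the 8 pools and 0 with the run set as a block over 8 pools. Above the detection level 39 rose and 8 fell at both ages, against 1.69 and 0.374, with the same limits. Of the 13 probes that rose at P17, 9 were also higher at P28, called or not. The difference between null and control that both pools shared had a standard deviation across probes of 0.562 at P17 and 0.794 at P28, on the log2 scale.

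For the difference of the genotype effect between ages, 0 probes were called in limma over all probes, and the smallest adjusted p was 0.062. Of 33010 probes 1530 had an unadjusted p under 0.05, less than the share of 0.05 expected with no change. This count thus shows no excess. The replicate block called 2, both with a lower effect at P28, and the detection level 15. Over named probes 2 genes differed. The effect on Dpp9 was lower at P28 than at P17 (log2 difference -2.83, SE 0.50, adjusted p = 0.026 over named probes, 0.34 over all), and so was that on Sult5a1 (-3.78, SE 0.64, 0.026 and 0.34). With the block over named probes Wfdc2 (3.74, adjusted p = 0.041), G6pc (1.99, 0.041) and Hsd3b4 (-4.47, 0.029) were called as well, and so was Trim59 with a higher effect at P28 (0.042). Trim59 was not well above background in P28 control liver and reached the detection level on 1 of 3 P17 null arrays, and Hsd3b4 reached it on 1 of 3 arrays in each group but P28 control, so the size of either difference is uncertain.

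**Figure D3:**
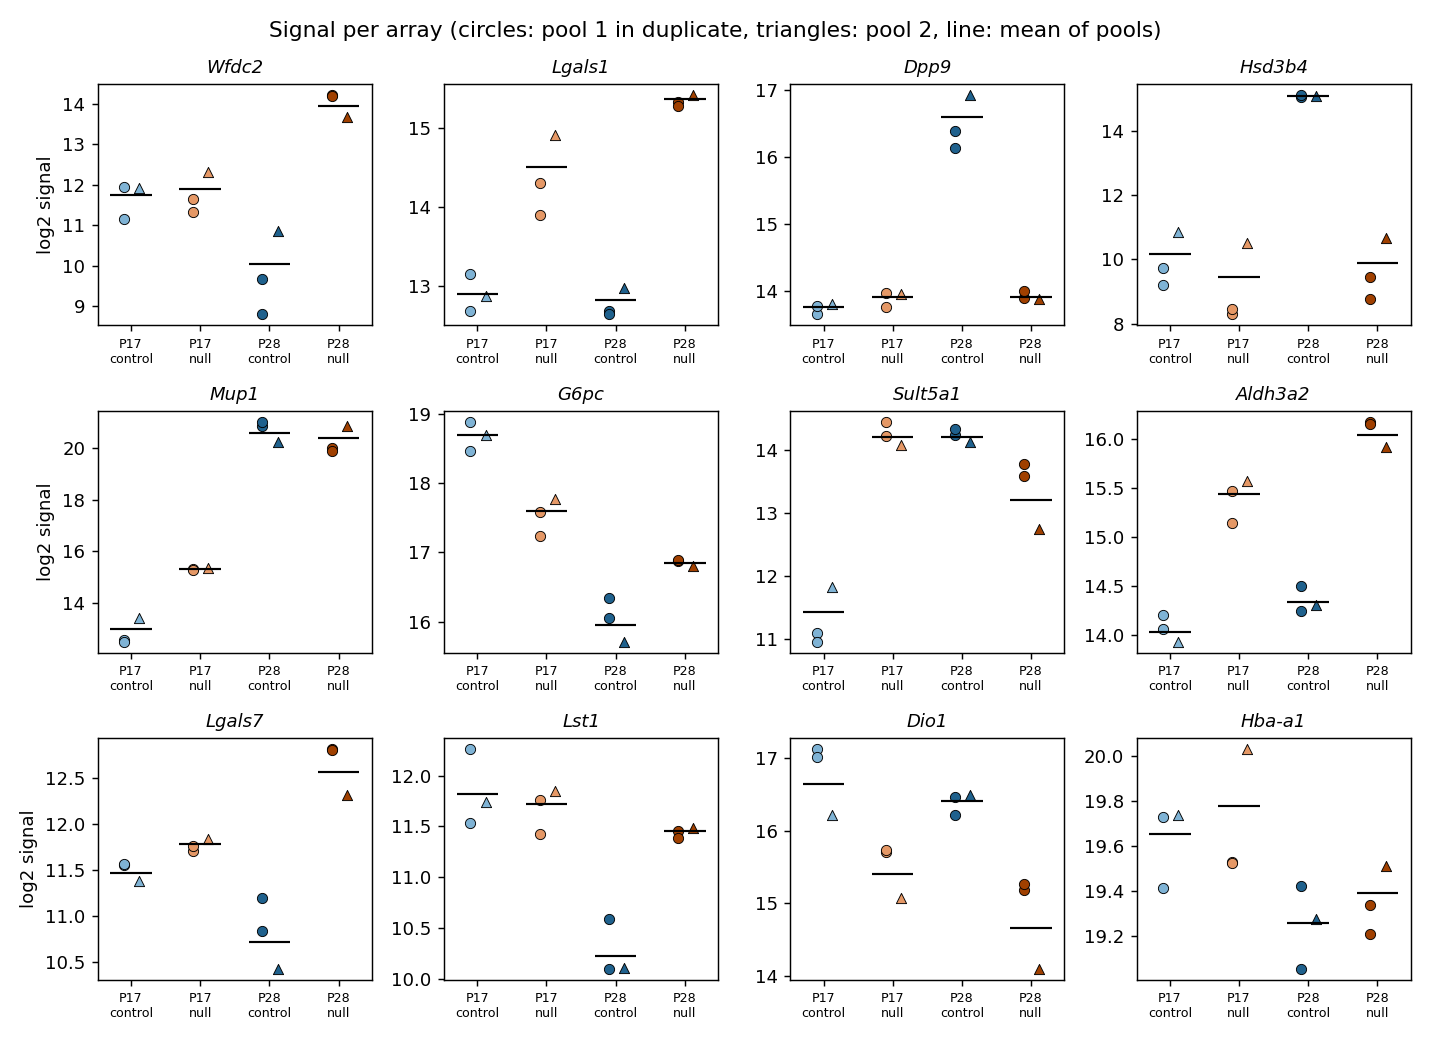
Normalized log2 signal of 12 genes on each array of the 4 groups (circles, duplicate arrays of the first pool; triangles, second pool; line, mean of the 2 pools). Dpp9 lies at 13.76, 13.91 and 13.92 in P17 control, P17 null and P28 null liver and at 16.60 in P28 control liver.

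In control liver, 58 probes changed between P17 and P28, 41 higher and 17 lower at P28. Mup1, which encodes a major urinary protein made by liver, rose 195-fold, from 12.98 ± 0.63 to 20.58 ± 0.50 (SD, n = 2 pools; log2 7.60, SE 0.49, adjusted p = 0.0022). Dpp9 rose 7.14-fold (2.84, SE 0.36, adjusted p = 0.036), and G6pc fell 6.69-fold, from 18.69 ± 0.02 to 15.95 ± 0.34 (-2.74, SE 0.35, adjusted p = 0.038). Within the second pools, which share 1 run set, the differences were 6.80, 3.12 and -2.99, and in the first pools, which do not, 8.41, 2.55 and -2.49. Leaving out any 1 of the 8 pools ended the calls of Dpp9 and G6pc but not that of Mup1, and the run set as a block over 8 pools ended all of them. Over named probes Hsd3b4 (log2 4.90, adjusted p = 0.014), Sult5a1 (2.79, 0.010) and the N-acetyltransferase-family gene Nat8f2 (1.70, 0.014) also rose. Lst1 (-1.59, 0.013) fell, to a value near the detection level. The unnamed probes mCG20398.1 and mCG6998.2, picked for their fall with Hdac3 loss at P28, were higher at P28 than at P17 in control liver. With arrays under the detection level raised to it, the rise was at least 74.8-fold and 51.7-fold (adjusted p = 0.014 and 0.012 in limma). For each, 2 of 3 P17 control arrays were over that level. The P28 genotype difference and this age difference share the P28 control pools. A value particular to these pools moves both, for these 2 probes and for Dpp9, Hsd3b4 and Lst1 as well. The rise with age is therefore no independent result beside the fall at P28. Hsd3b4 also passed the detection level only through P28 control liver.

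In Hdac3-null liver, 3 probes changed between the ages, 2 higher and 1 lower at P28, none of them named. Of 33010 probes 2241 had an unadjusted p under 0.05, more than the share of 0.05 expected with no change. Over named probes Mup1 rose 33.3-fold (log2 5.06, SE 0.49, adjusted p = 0.0017, and 0.058 over all probes). Dpp9 differed by 0.01 (SE 0.36), G6pc by -0.75 (SE 0.35) and Hsd3b4 by 0.44 (SE 0.82). The detection level gave 152 calls in control and 100 in null liver, and together with the replicate block the order turned, with 420 in control and 486 in null liver. With the run set as a block over 8 pools the counts were 2 and 0, and leaving out 1 pool gave 13 to 40 in control and 0 to 1 in null liver. Mup1, Hsd3b4, Ear1, Hba-a1 and Bcl2a1b belong to families of near-identical genes, and the values of their probes are uncertain for the single gene.

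The age difference and the genotype difference were set against each other across 12765 probes without a symbol above the detection level, with the age difference taken from the second control pools and the genotype difference from the first pools, which share no pool or run set. Probes are not independent replicates. Both differences still hold control liver of the same age, from different pools. Levels that both pools of P17 control liver share raise r at P17, and those that both pools of P28 control liver share lower it at P28. Neither sign alone therefore tells of an effect of Hdac3 loss. At P17 the correlation was r = 0.34 (rho = 0.28), and at P28 r = -0.13 (rho = -0.07). With the pools exchanged, r was 0.22 at P17 and -0.20 at P28.

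**Figure D4:**
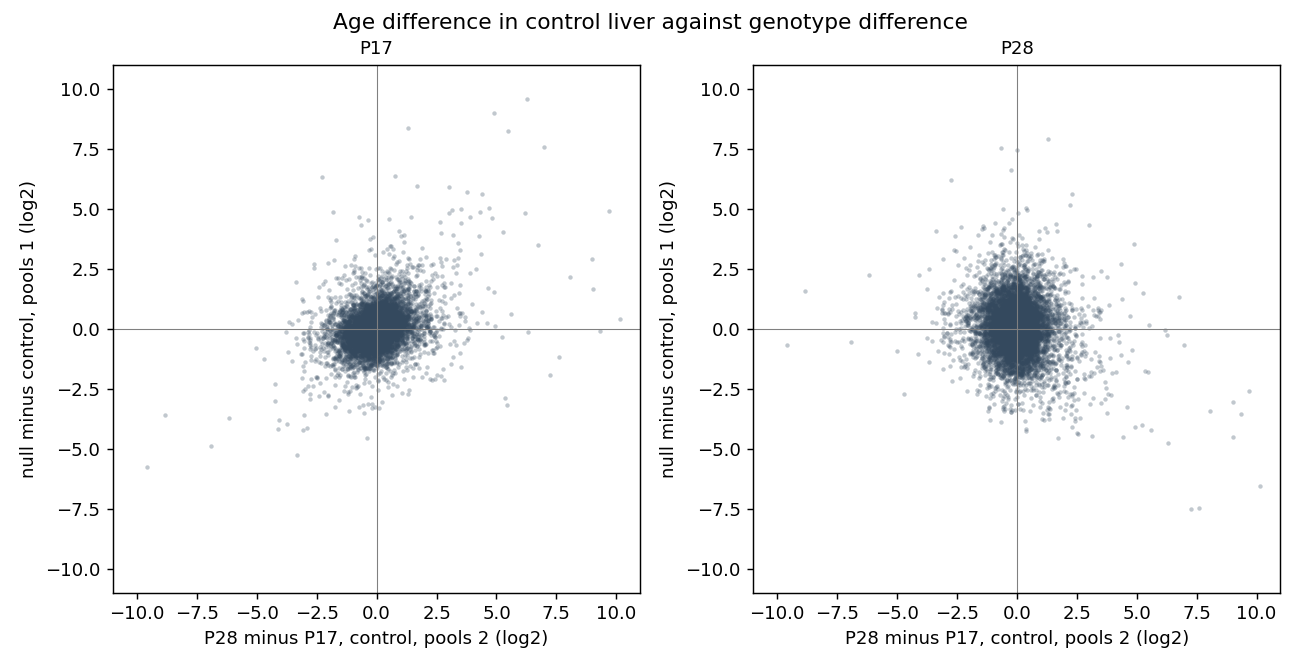
P28 minus P17 log2 difference in control liver, second pools (x axis), against null minus control log2 difference, first pools (y axis), at P17 (left) and P28 (right), for 12765 probes without a symbol above the detection level. The cloud leans upward at P17 (r = 0.34) and slightly downward at P28 (r = -0.13).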

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

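The comparisons in this part were chosen after the values were seen. For 5 of the 24 named genes, null minus control had 1 sign in both pools at P17 and the opposite sign in both pools at P28. Among 12902 probes above the detection level 15.4% did so, against 12.5% expected if every sign were random, and 37% had 1 sign in all 4 differences, so the direction alone carries little weight. The 2 pools of an age had the same sign for 71.6% of these probes at P17 and 72.2% at P28. Signs are thus not random, 12.5% is too low an expectation, and 15.4% shows no excess of opposite effects. The test of the difference itself called none of the 5 over all probes (adjusted p from 0.34 to 0.96 in limma), and called Sult5a1 and Dpp9 over named probes; with the replicate block by pool it also called G6pc (0.041) and Trim59 (0.042) over named probes.

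The effect on the sulfotransferase gene Sult5a1 was 3.32 and 2.26 in the P17 pools and -0.61 and -1.38 in the P28 pools, a difference of -3.78 between ages (SE 0.64, adjusted p = 0.026 over named probes). Dpp9 differed between ages by -2.83 (SE 0.50, 0.026), with P17 values of 0.15 and 0.14 that lie within 1 SE of 0. G6pc was lower in both P17 null pools (-1.27 and -0.93) and higher in both P28 null pools (0.69 and 1.10), a difference of 1.99 (SE 0.49, 0.064). Trim59 differed by 3.85 between ages (SE 0.78, 0.064), but it was not well above background in P28 control liver and reached the detection level on 1 of 3 P17 null arrays, so the size is uncertain. Nat8f2 differed by -1.45 (adjusted p = 0.16 over named probes).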

How the results depend on the processing

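Counts are given in 1 order: changed at P17, changed at P28, effect different between ages, age in control, age in null, shared by both ages, and genotype over both ages together. The reported counts were 15, 131, 0, 58, 3, 5 and 133. Fewer calls came from the deposited values without further normalization (2, 13, 0, 22, 2, 1, 13), which is also the authors' value table, from technical replicate 1 alone (10, 65, 0, 49, 2, 3, 68) and from technical replicate 2 alone (9, 79, 0, 47, 2, 3, 78). Scaling to the 75th percentile gave 10, 89, 0, 53, 2, 3 and 129. More calls came from normexp correction (25, 190, 3, 71, 28, 10, 185), an offset in place of the floor (40, 260, 3, 95, 32, 17, 212), a signal-to-noise score of 3 on every array (114, 407, 6, 105, 80, 54, 336) and eBayes with trend and robust (126, 411, 39, 149, 122, 59, 354). Only the pools compared gave 0, 0, 0, 10 and 0 for the first 5, with fewer pools for the spread. The replicate block by pool gave 5, 246, 2, 66, 2, 3 and 184.

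Unaveraged arrays gave 195, 605, 73, 215, 175, 81 and 443 with the pool as a random block, and 392, 1618, 225, 612, 585, 189 and 766 with the replicate block by labelled number. With the run set as a block on 12 arrays the counts were 2304, 6031, 2235, 415, 382, 990 and 1198. The correlation estimated within pools was then -0.46, a negative value that a shared pool effect cannot give, so these p-values are too small. The run set as a block over 8 pools, added after the data were seen, gave 0, 5, 0, 2, 0, 0 and 49 with fewer residual degrees of freedom. Also added then, the detection level gave 96, 521, 15, 152, 100, 47 and 368, and with the replicate block by pool 275, 1739, 119, 420, 486, 153 and 892. Without 1 pool the ranges were 0 to 5, 0 to 28, 0 to 0, 13 to 40, 0 to 1, 0 to 0 and 4 to 38; a group left with 1 pool is assumed to vary like the others. Where no construction is named, the cause was not tested. The floor at the 20th percentile, no filter, no probe with a bad spot and a log2 fold change of at least 1 moved no count by over 1.5 times.

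Among the genes named in the text, which were in part chosen after changes of sign had been seen, no called log2 difference changed sign, but most calls were lost in some settings. Of the 12 called differences of genes and probes named in the text, 11 were no longer called without either P28 control pool, 9 without either P28 null pool, 5 to 7 without a P17 pool, 11 with the run set as a block over 8 pools, 11 with only the pools compared, 6 on the deposited values, 5 and 2 with technical replicate 1 or 2 alone, 3 with scaling to the 75th percentile and 1 with the floor at the 20th. Signs turned for small differences that were not called. Ear1 at P17 was -0.01 with technical replicate 1 alone, -0.02 with the replicate block by labelled number, -0.05 with the run set block on 12 arrays, and ran from -0.26 to 0.32 without 1 pool. Without 1 pool, P17 values also ran from -0.13 to 0.37 for Hba-a1, -1.79 to 0.35 for Hsd3b4, -0.22 to 0.03 for Lst1, -1.84 to 0.05 for mCG20398.1, -0.48 to 0.53 for Stat5b and -0.25 to 0.59 for Wfdc2, and P28 values from -0.66 to 0.26 for Mup1. List tests under any setting were not run, since too few members had a name. Low signal limits what can be called: 58.6% of scanner readings had a score under 3.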

Other observations

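The tests of the pool difference and of the P17 age relation were chosen after their results were seen; the P28 age relation was prompted by the values of Dpp9, Hsd3b4, Wfdc2 and Ear1, and was tested on probes without a symbol. A comparison of genotype over both ages together, added after the data were seen, called 133 probes, 98 higher and 35 lower in Hdac3-null liver (limma, 4 against 4 pools), and 184 with the replicate block by pool. It called 49 with the run set as a block over 8 pools and 13 on the deposited values without further normalization. Of the 34 splits of the 8 pools into 4 and 4 that could be fitted with no block, 2 called at least 133, the real one among them. Chance is therefore not excluded at 0.05. The other was the split by pool number with 1162 calls, which points to a structure of the samples, and each remaining split called 0. Among the 8 splits that part all 4 pairs of pools, with the block, the real one called 184 and the highest other 0; so few splits cannot give a share under 0.05.

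First and second pools stood apart in every group. Chance differences between mice would leave the pool differences of the 4 groups unrelated, yet the lowest of 6 correlations between groups was 0.52, which argues against them as the whole cause. Separate array runs of the 2 pools predict such a shared difference. RNA handling or harvest shared by the second pools may give the same value and was not told apart from the array run.

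Across probes, the P17 genotype difference went in part with the age difference of control liver. A hypothesis is that loss of Hdac3 brings part of the P17 transcripts nearer to P28 control levels. The correlation of second-pool age differences with first-pool P17 genotype differences was 0.34, and 0.22 with the pools exchanged. Over all probes without a symbol it was only 0.19, and 0.09 with the pools exchanged. Both differences subtract P17 control liver, so levels that both of its pools share raise r without such a shift. These values therefore do not decide for the hypothesis. Of 216 probes at least 2 higher with age in the second control pools, 72.2% were higher in the P17 null first pool, with a median of 0.57. The share over all probes is not given here, and P17 control liver enters both of these differences too. A few very large differences do not account for the value of 0.34 (rank correlation 0.28, and 0.15 with the pools exchanged). Removal of the trend of both differences with mean signal left r at 0.34, and at 0.22 with the pools exchanged. This argues against such a trend as the source of r. Differences between litters in maturity at P17 stay open and were not tested here.

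At P28 the relation ran the other way, though weakly. If loss of Hdac3 shifts P28 liver towards P17 control levels, the correlation should lie below -0.1; it was -0.13, and -0.20 with the pools exchanged, but the rank correlation was -0.07 (-0.17 with the pools exchanged) and over all probes without a symbol r was -0.02, and -0.09 with the pools exchanged. A genotype difference that is the same at both ages was expected to give a like r at P17, and r there was 0.34. This does not decide against it. The age difference adds P28 control liver and subtracts P17 control liver, and each genotype difference subtracts the control of its age. Levels that both pools of a control group share thus lower r at P28 and raise it at P17, whatever the genotype effect. For the same reason a value below -0.1 does not by itself speak for the shift. Removal of the trend of both differences with mean signal left r at -0.13, and at -0.20 with the pools exchanged. This argues against such a trend as the source of r. Of the same 216 probes 64.4% were lower in the P28 null first pool, with a median of -0.86, and of 152 probes at least 2 lower with age 62.5% were higher, with a median of 0.32. The shares over all probes are not given here, and P28 control liver enters both differences. Probes that passed the detection level only through P28 control liver were also chosen to be high there, which favours lower null values. Whether the relation rests on probes with large age differences stays open, since the rank correlations of the pool arrangements disagree, and a candidate test is the same comparison in further pools with named probes.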
